A study of Mus musculus with 16 samples.

How the data were processed

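RNA was isolated from primary cortical neurons of C57BL/6 mouse embryos (embryonic day 17.5 to 19.5), with 1 litter pooled per biological replicate per the labels. AAV carrying a hairpin was added on day 8 in vitro and cells were collected on day 13. Silenced cultures received tetrodotoxin at 1 to 2 µM for 24 hours and D-AP5 at 100 µM for 6 hours. Stranded poly(A) libraries with 12 PCR cycles were made from RNA with a RIN above 8 and sequenced as paired reads of 100 bases, at a stated depth of 30 to 55 M fragments. Per the labels, the authors counted reads per gene with featureCounts 2.0.1 on mm10 after FastQC, and the deposited tables hold raw counts, with no normalization. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. The description of the shNup153 samples names the control virus while their titles name the knockdown hairpin, and groups were taken from the titles.

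The basal table held 26371 gene symbols and the silenced one 55304, of which 20081 had no counts. All 26371 symbols of the basal table occur in the silenced table, where they hold 99.88% of the counts. How the basal table was reduced is not stated. At basal state, 2 columns carry the same name, and a replicate of shNup153-1 that the labels would lead one to look for has no column. Both columns were left out, since neither could be assigned to a sample by name, so each hairpin had 2 basal libraries. Total counts per library ranged from 26863535 to 56299817, and the 10 most abundant genes held 4.15% to 5.44% of them.

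Each column was compared with the others down the table, since genes stand in the same order in all. A search for the line offset that best aligns the columns found the shNup153-1 columns in register up to line 16419 and displaced by 1, 2, 3 and 4 lines beyond it. Shifted back, their correlation with shControl across genes over the 9952 lines was 0.9659, against 0.0923 as deposited. Comparisons of shNup153-1 with another group used the lines up to 16399, a margin of 20 lines, with library totals from all lines. This departed from the design, in which all lines were to be used, and was decided after seeing the data. In simulated columns the search found all 3 planted steps to within 1 line. The fit of all lines as deposited and the fit of shifted columns were added as alternatives for comparisons with shNup153-1. The fit for basal shNup153-2 and the joint fit of both states kept the shNup153-1 columns as deposited over all lines. For shNup153-2 only the fit of the groups compared left those columns out, and for the joint fit no alternative did.

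Counts were modelled with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM factors and tested with the quasi-likelihood F test in a means model of the groups, with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05 (FDR). The 3 basal groups were fitted together, the silenced groups in their own fit, and the interaction and the comparison of states in a joint fit of all 14 libraries over the shared symbols. Counts-per-million values (CPM) use the scaled library totals. A shared change is a gene past the threshold in both comparisons with the same sign. Of 33 gene lists fixed beforehand, those with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with the correlation estimated and with fry. List members were counted from the edgeR tests, over all genes and adjusted over the list alone. None of the lists was taken from these libraries.

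Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Nup153 and Hdac1 and, for the change shared by both hairpins and for silenced cultures, the 12 largest rises and the 12 largest falls past the threshold whose knockdown libraries all lie on 1 side of all control libraries, with a mean of at least 1 CPM in the higher group. Predicted and clone-named genes were left out. For other comparisons it named 5 each way, and for each list up to 4 members with the smallest p. A gene quoted from a list in a further comparison was named there because the rule had named it elsewhere, and the members quoted from the blocked fit (Msmo1, Sqle, Atf3 and Xbp1) were chosen after their values were seen.

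Whether replicate numbers pair the libraries was tested on residual log2 CPM. In the silenced table libraries of the same number correlated across genes at 0.29, 0.57 and 0.62, so the fit with replicate number as a block is given beside the unblocked one. The labels do not say that equal numbers share a litter, and so few libraries per group cannot establish pairing. In the basal table each knockdown hairpin has 2 libraries, whose residuals mirror each other, so values of both signs were fixed in advance. Residuals of shNup153-1 replicate 1 went with shControl 2 and 4 (0.65 and 0.38), and those of replicate 2 with shControl 1 and 3 (0.58 and 0.55). Libraries of equal number had -0.58 and -0.65 there, so the number does not describe this grouping, which the main model does not hold. The block serves as an alternative only. Positions come from the GENCODE annotation of the same genome build, in which all 451 named genes had 1 gene of that symbol. For 3′ UTR sites, every 7-base sequence was scored by the log2 fold changes of genes with and without it, after removal of UTR length and GC content. In simulated data all 5 planted sites ranked first, but only sites held by many genes were planted, so the search for rarer ones was not tested. The trend of log2 CPM with transcript length in each library was removed with an offset as an alternative added after seeing the data. On simulated counts for 14529 genes with a planted length trend, 183 of 200 changed genes were found without the offset beside 95 other calls, and 189 with it beside 8 others.

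The models were tested on simulated counts with the study's group sizes. A change of 4-fold was found in 78.8% of changed genes for shNup153-1, 80.3% for shNup153-2, 89.4% in silenced cultures and 31.8% for the interaction, and a change of 2-fold in 7.46%, 5.97%, 34.3% and 0. Of the calls made, 4.84%, 5%, 11.5% and 12.5% were false. Alternatives were RLE and upper-quartile factors, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a stricter threshold, a minimum log2 change of 0.5, the replicate block, fits of only the groups compared, and each library left out in turn. Added after seeing the data were those on line offsets and transcript length, genes without hairpin sites, and fits without basal shControl libraries 2 and 4, whose length trend and astrocyte or respiratory chain levels stood apart. Where leaving out a library left 1 sample in a group, its spread was taken to be that of the other groups. In a check for mixed-up samples, added after seeing the data, 1 of 14 libraries did not match the pooled litters that the labels state, and it was kept. Shared controls were examined with 20 simulated data sets and with the 6 divisions of the shControl libraries. Site scans and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Intervals on ratios of counts are 95% exact intervals and cover counting error only. Results for some individual genes that the naming rules selected are not reported here.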

Results

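Poly(A) RNA from mouse primary cortical neurons was sequenced after AAV delivery of short hairpin RNAs against Nup153, a nucleoporin of the nuclear basket, the part of the nuclear pore that faces the chromatin. The labels name the link between Nup153, the histone deacetylase HDAC1 and neuronal responsiveness as the subject of the series. Cultures at basal state held 4 libraries with a control hairpin (shControl), 2 with the hairpin shNup153-1 and 2 with the hairpin shNup153-2. Silenced cultures held 3 libraries with shControl and 3 with shNup153-2. Silencing combined tetrodotoxin, which blocks sodium channels and so action potentials, with D-AP5, which blocks NMDA receptors. Total counts per library ranged from 26863535 to 56299817. They were 56299817, 28940314, 29538152 and 31220182 for basal shControl, 26863535 and 30896958 for basal shNup153-1, and 44044312 and 36935049 for basal shNup153-2. The silenced shControl libraries held 36096417, 32995121 and 38421417 counts and the silenced shNup153-2 libraries 44470636, 27975274 and 40443478.

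The first comparison asked how far the target transcript was reduced. Levels are counts-per-million values (CPM). Nup153 (chromosome 13, 46679905 to 46727940, mm10) stood at 72.0 ± 19.0 CPM (SD, n = 4) in basal shControl cultures, 22.8 ± 7.96 (SD, n = 2) with shNup153-1 and 12.6 ± 1.39 (SD, n = 2) with shNup153-2. In silenced cultures it stood at 57.5 ± 6.65 CPM (SD, n = 3) with shControl and 10.9 ± 2.08 (SD, n = 3) with shNup153-2. The log2 fold change was -1.67 (SE 0.32) with shNup153-1, with a Benjamini-Hochberg (BH) adjusted p of 0.0122 in the edgeR quasi-likelihood test. With shNup153-2 it was -2.52 (SE 0.32, edgeR BH-adjusted p = 0.00376) at basal state and -2.40 (SE 0.17, edgeR BH-adjusted p = 0.00534) under silencing. Per the labels, samples were processed only where the knockdown sufficed, so these levels reflect a selection as well as the hairpins. Leaving out shNup153-1 replicate 1 gave an edgeR BH-adjusted p of 0.103, leaving out basal shNup153-2 replicate 1 or 2 gave 0.059 or 0.0772, and leaving out silenced shNup153-2 replicate 1 gave 0.0656. Of 26 nucleoporin genes tested with shNup153-1, 2 fell, namely Nup153 and Ahctf1, a factor of postmitotic pore assembly (SE 0.22, edgeR BH-adjusted p = 0.0211). Ndc1, a membrane anchor of the pore, rose with shNup153-2 at basal state (0.93, SE 0.21, edgeR BH-adjusted p = 0.0272) and under silencing (0.67, SE 0.11, edgeR BH-adjusted p = 0.0297).

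**Figure D1:**
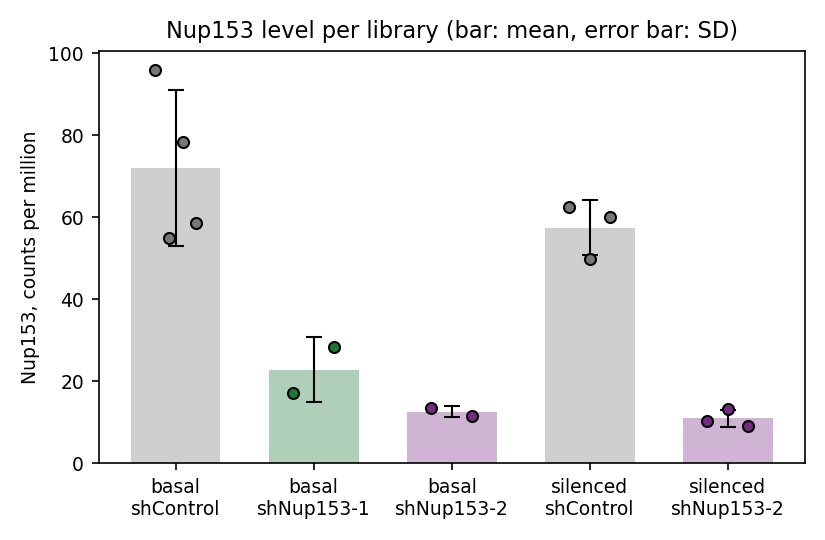
Nup153 in counts-per-million values in each library (points), with the mean and SD of each group. The shControl groups average 72.0 and 57.5, and the groups with a hairpin against Nup153 average 22.8, 12.6 and 10.9.

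The deposited basal table held the shNup153-1 counts out of register with the gene symbols in its lower part. Across genes, the correlation of mean log2 CPM between shNup153-1 and shControl was 0.9755 over the first 16399 lines and 0.0923 over the 9952 lines after the break. Values of the shNup153-1 columns sat 1 line off from line 16420, and 2, 3 and 4 lines off from lines 18308, 19510 and 21058. Comparisons that use shNup153-1 as an effect therefore cover the first 16399 lines, and genes further down the table have no value with that hairpin here. The basal fit for shNup153-2 and the joint fit of all 14 libraries covered all lines, with the shNup153-1 columns as deposited. Beyond the break, counts set against wrong symbols thus entered the filter, scaling and spread estimates of those fits.

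**Figure D2:**
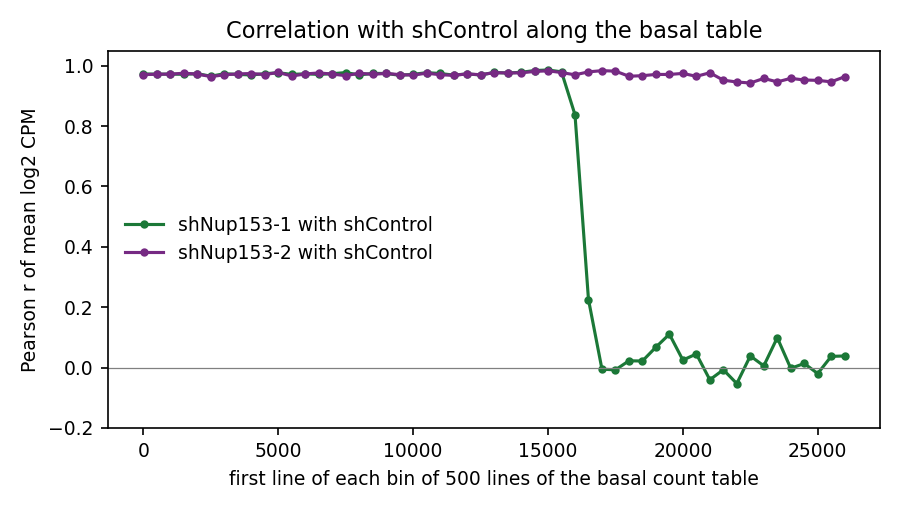
Pearson correlation with basal shControl, across the genes of each successive block of 500 lines of the deposited table, for shNup153-1 and shNup153-2. The shNup153-1 line drops from 0.986 in the block from line 15001 to -0.00564 in the block from line 17001.

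Next, the shared change with both hairpins at basal state was asked for, since both hairpins were made against the same transcript. Activity-regulated transcripts and several synaptic and channel transcripts stood among the genes that rose. Npas4, a neuron-specific transcription factor induced by activity, went from 2.70 CPM to 35.6 with shNup153-1 (log2 fold change 3.70, SE 0.40, edgeR BH-adjusted p = 0.00201) and 19.8 with shNup153-2 (2.87, SE 0.39, edgeR BH-adjusted p = 0.0044). Panx2, a channel-forming pannexin (chromosome 15, 89059734 to 89073567), rose from 24.6 ± 2.12 CPM (SD, n = 4) to 175 ± 19.1 (SD, n = 2) and 172 ± 16.6 (SD, n = 2), log2 fold changes of 2.83 and 2.81 with edgeR BH-adjusted p of 0.000262 and 0.00056. Rph3a, which encodes the synaptic vesicle protein rabphilin, rose by 3.08 (SE 0.24) and 3.35 (SE 0.25), with edgeR BH-adjusted p of 0.00163 and 0.000652. Its 3′ UTR holds the 7-base sequence GTCGCCC, present in 4.32% of the searched genes that rose with shNup153-1 and 1.23% of the others. GTCGCCC was picked for its highest score over the basal comparisons of both hairpins, so these shares are no independent test of it. Ndrg1, a gene induced by hypoxia and mutated in a demyelinating neuropathy (chromosome 15, 66929318 to 66969640), fell from 311 ± 90.3 CPM (SD, n = 4) to 18.5 and 37.5, log2 fold changes of -4.08 (SE 0.37) and -3.05 (SE 0.35) with edgeR BH-adjusted p of 0.00163 and 0.00262. Antisense neighbours overlap 8.4% of the exons of Ndrg1, and how the strands were counted is not given in the sources used here. With shNup153-2, Npas4 and Ndrg1 were no longer past FDR 0.05 without shNup153-2 replicate 2 (edgeR BH-adjusted p of 0.0588 and 0.0552).

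In all, 592 of 14529 genes changed the same way with both hairpins at FDR 0.05, of which 378 rose and 214 fell, and 11 changed in opposite directions. With shNup153-1 alone 947 genes rose and 1024 fell, and with shNup153-2, over 21292 genes, 1083 rose and 668 fell. Among the 14529 genes, 939 rose and 540 fell with shNup153-2, for which chance overlap with the shNup153-1 calls would give 61.2 rises and 38.1 falls, but both comparisons used the same 4 shControl libraries. Data simulated with shared controls and no effect of either hairpin gave a covariance of the log2 fold changes of 0.0534 and a correlation of 0.326, against 0.333 and 0.485 in the data. Each gene was drawn independently in these simulations. Trends that run across genes within a library, such as that with transcript length, were thus not simulated, and the gap is no full test. With the controls divided between the hairpins, the 6 possible divisions gave 86, 433, 111, 98, 443 and 90 shared rises, where chance gives 5.09, 260, 6.81, 5.79, 91.8 and 4.18. Shared falls were 46, 381, 56, 56, 276 and 53, where chance gives 3.82, 266, 5, 4.58, 64.4 and 3.13. The correlation was 0.0667 in the second of these divisions, with shControl libraries 1 and 3 set against shNup153-1, and 0.357 to 0.512 in the other 5. The count fell to 291 without shControl replicate 4, 206 and 323 without either shNup153-1 library, and 64 and 60 without either shNup153-2 library.

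Of the genes named for the largest shared rise, the transcription factor gene Ovol2 rose by 3.50 and 4.70, and the guanylate cyclase gene Gucy2g by 4.36 and 3.73. Mir670hg, a microRNA host transcript, rose by 3.55 and 2.82, the potassium channel subunit gene Kcng4 by 4.13 and 1.83, and Alkal2, a ligand gene of the receptor ALK, by 2.12 and 3.83. Nr4a1, an activity-induced nuclear receptor gene, rose by 2.60 and 3.29, Stac2 by 2.99 and 2.89, Tcim by 3.01 and 2.69, and the amino acid transporter gene Slc7a8 by 2.68 and 3.06. Among the named falls, Slc17a9, which encodes the vesicular nucleotide transporter, changed by -2.80 and -3.79 and Hes5, a Notch target, by -3.16 and -4.95. Pabpc1l changed by -3.45 and -3.52, Hhipl2 by -2.22 and -4.43, Nmrk2 by -2.60 and -3.96, Fut7 by -2.83 and -3.63, Iyd by -3.43 and -3.00, and Trim72 by -3.27 and -2.98. Kdr, the endothelial receptor for VEGF, held 2 counts over both shNup153-1 libraries, a shControl to shNup153-1 ratio of 101 (95% exact interval 27.8 to 835). Lbx2 held 3 counts with shNup153-1 and 2 with shNup153-2, ratios of 28.5 (9.62 to 139) and 59.9 (16.4 to 498), intervals that cover counting error only. Antisense neighbours overlap 35.1% of the exons of Alkal2, 31.8% of Hes5, 27.6% of Trim72, 18.7% of Tcim and 14.6% of Nmrk2. With limma-voom, Hes5 and Kdr were not past FDR 0.05 with either hairpin, nor was Lbx2 with shNup153-1. With every library left out in turn, 14 of 25 named genes stayed past FDR with shNup153-1 and 6 of 25 with shNup153-2.

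Immediate early genes, the first transcripts that neuronal activity induces, were higher with both hairpins. Of 29 members, 13 rose and none fell with shNup153-1, among them Dusp1 (2.12), Egr4 (2.06) and Ier2 (2.47), and 13 rose and none fell with shNup153-2, among them Nr4a3 (2.94) and Trib1 (1.91). Adjusted over the list alone, 17 rose with shNup153-1, and 17 rose and 1 fell with shNup153-2. The list medians were 1.16 and 1.22 (camera BH-adjusted p = 1.25e-06 and 2.19e-07, adjusted p = 0.805 and 0.864 with an estimated correlation). The mean log2 CPM of the list lay between 4.03 and 4.67 in the 4 knockdown libraries and between 2.70 and 3.45 in the 4 shControl libraries. Late activity-regulated genes, which encode secreted and synaptic effectors, went up as a group with shNup153-2. There, 15 of 29 rose and 1 fell (20 and 3 adjusted over the list alone, median 0.96, camera BH-adjusted p = 1.02e-06, adjusted p = 0.464 with an estimated correlation). Acan, a perineuronal net proteoglycan, rose by 3.65 (SE 0.25), Pcsk1, a prohormone convertase, by 2.52 (SE 0.29), Vgf by 3.08 (SE 0.38) and the neurotrophin Bdnf by 3.05 (SE 0.41). With shNup153-1, 8 rose and 3 fell, with Pcsk1 at 2.04 and Scg2 at 2.09 and the kinase Plk2 at -1.64 (edgeR fit, camera BH-adjusted p = 0.103). The difference between the hairpins passed FDR for Acan (2.78, SE 0.30, edgeR BH-adjusted p = 0.00798).

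**Figure D3:**
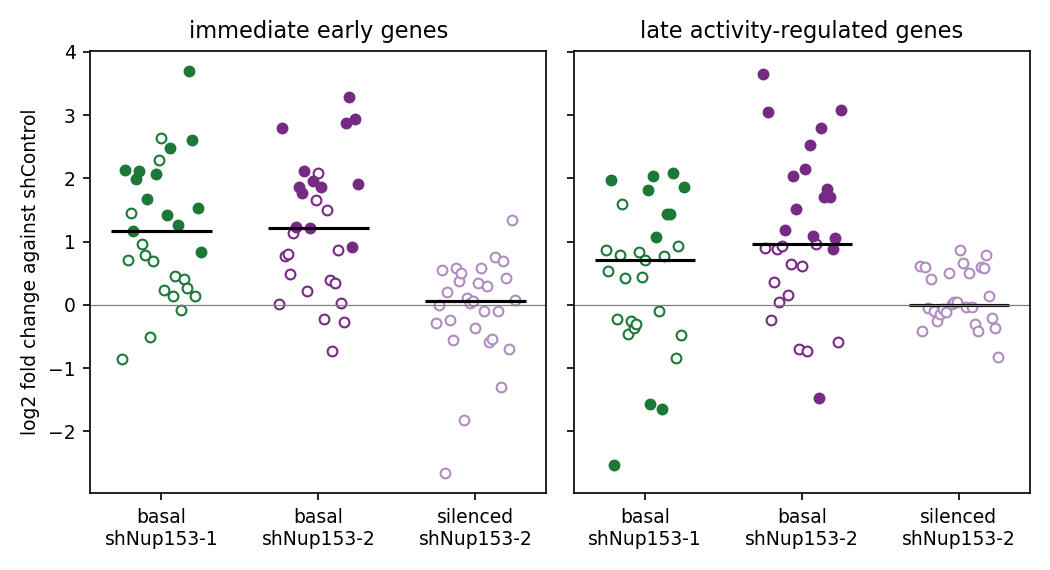
Log2 fold change against shControl of each immediate early gene and late activity-regulated gene with shNup153-1 and shNup153-2 at basal state and with shNup153-2 under silencing. Filled points passed FDR 0.05 and lines mark medians, which for the immediate early genes were 1.16, 1.22 and 0.07.

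Potassium and HCN channel genes, which set excitability, rose with shNup153-2 in 17 of 53 cases with no fall (23 and 2 adjusted over the list alone). Their median was 0.79 (camera BH-adjusted p = 1.9e-08, adjusted p = 0.464 with an estimated correlation). Hcn2 rose by 2.63 (SE 0.25), Kcnc4 by 2.14 (SE 0.20) and Hcn4 by 1.81 (SE 0.20), and with shNup153-1 Hcn2 rose by 2.67 (SE 0.24) and Kcnc4 by 1.61 (SE 0.19). With shNup153-1 8 of 51 rose, but the median was -0.01 and the list did not pass the list test (edgeR fit, camera BH-adjusted p = 0.274). Of 43 genes for excitatory synapse receptors and scaffolds, 8 rose and 2 fell with shNup153-2 (16 and 2 adjusted over the list alone, camera BH-adjusted p = 0.000592, adjusted p = 0.876 with an estimated correlation), with Shank3 at 2.14, Dlgap3 at 2.10 and Shank2 at 2.25, while with shNup153-1 3 rose and 4 fell with a median of -0.28 (camera BH-adjusted p = 0.209). Of 38 genes of presynaptic vesicle release, 7 rose with shNup153-1 (9 adjusted over the list alone, camera BH-adjusted p = 0.00737, adjusted p = 0.805 with an estimated correlation), with Syt2 at 2.40 and Vamp1 at 2.01. With shNup153-2, 6 rose, with Bsn at 2.21, and 2 fell, with Syt5 at -2.59 (16 and 2 adjusted over the list alone, camera BH-adjusted p = 0.000835, adjusted p = 0.864 with an estimated correlation). Of 62 axon guidance and adhesion genes, 9 rose with shNup153-2, with Ephb2 at 1.53 and Sema3a at 1.19 (17 and 2 adjusted over the list alone, camera BH-adjusted p = 0.000297, adjusted p = 0.885 with an estimated correlation), while with shNup153-1 3 rose and 8 fell with a median of -0.23 (camera BH-adjusted p = 0.209). Of 55 clustered protocadherin genes, 5 rose (14 adjusted over the list alone, median 0.72, camera BH-adjusted p = 9.46e-07, adjusted p = 0.876 with an estimated correlation). Subunits of the nuclear-encoded respiratory chain had a median of -0.65, with 1 of 53 past FDR, Sdha at -1.05 (camera BH-adjusted p = 0.000239, adjusted p = 0.885 with an estimated correlation). The respiratory chain list averaged 6.21, 7.39, 6.28 and 6.95 log2 CPM in the shControl libraries and 6.15 and 6.25 with shNup153-2.

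Markers of other cell types differed between the groups as well. Of 17 oligodendrocyte lineage markers, 13 rose and none fell with shNup153-1 (15 adjusted over the list alone, median 2.42, camera BH-adjusted p = 5.05e-11, adjusted p = 0.316 with an estimated correlation). Enpp6 rose by 5.49 (SE 0.45). The list averaged 4.21 and 3.56 log2 CPM in the shNup153-1 libraries, 0.31 to 1.16 in shControl and 0.40 and 0.61 with shNup153-2. Some of these markers also differed between silenced and basal shControl cultures, as given below. With 2 shNup153-1 libraries, the hairpin and the cell mix of those cultures cannot be told apart. Astrocyte markers averaged 6.33, 4.11, 5.91 and 5.62 log2 CPM in shControl, 5.37 and 6.84 with shNup153-1 and 6.17 and 6.49 with shNup153-2, so the spread between shControl libraries was as wide as the difference between groups. Of 20 astrocyte markers, 2 rose with shNup153-1, with Acsbg1 at 0.85 and S100b at 1.27 (camera BH-adjusted p = 0.0395, adjusted p = 0.822 with an estimated correlation). With the trend of transcript length removed the list was not past the threshold (camera BH-adjusted p = 0.06), with a median of 0.65 against 0.63. Of 22 GABAergic interneuron markers, 3 rose with shNup153-1, with the vesicular transporter gene Slc32a1 at 1.72 (camera BH-adjusted p = 0.0395, adjusted p = 0.822 with an estimated correlation).

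With shNup153-1, 4 of 23 cholesterol synthesis genes fell and none rose (11 adjusted over the list alone, median -0.93, camera BH-adjusted p = 0.00118, adjusted p = 0.822 with an estimated correlation). Hsd17b7 changed by -2.90 (SE 0.42) and Lss by -1.57 (SE 0.30). Of 30 nuclear transport factors, 3 fell with shNup153-1, with the importin gene Kpna1 at -2.01 (SE 0.25) and the exportin gene Xpo5 at -0.88 (SE 0.17) (camera BH-adjusted p = 0.0459, adjusted p = 0.805 with an estimated correlation). With the trend of transcript length removed this list was not past the threshold with shNup153-1 (median -0.33 against -0.38, camera BH-adjusted p = 0.0761) and was with shNup153-2 (median -0.26 against -0.14, camera BH-adjusted p = 0.00998 against 0.147), as was the lamin list with shNup153-2 (0.0343 against 0.231). Kpna1 holds 3 copies of the 7-base sequence TGGCTTT in its 3′ untranslated region (UTR). This sequence was present in 434 of 987 searched genes that fell with shNup153-1 and in 21.9% of the others (odds ratio 2.8, 95% interval 2.45 to 3.2). It was picked for its lowest score in shNup153-1 replicate 1 against shControl replicates 1 and 2, libraries also in this fit. The odds ratio is therefore no independent test. In replicate 2 against shControl replicates 3 and 4, TGGCTTT again had the lowest score (z -16.79). Of 19 lamin and chromatin architecture genes, Sun2 fell (-1.06, SE 0.23, camera BH-adjusted p = 0.0395 for the list, adjusted p = 0.805 with an estimated correlation). Lss holds 2 copies of TGGCTTT, and Hsd17b7, Sun2 and, among the named falls above, Pabpc1l hold 1 each. Nup153 itself also holds 2 copies, as does Syt2, which rose with shNup153-1.

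Hdac1 (chromosome 4, 129516104 to 129542713), the deacetylase that the labels name, did not pass FDR with either hairpin. Its log2 fold change was -0.29 (SE 0.19, edgeR BH-adjusted p = 0.34) with shNup153-1 and -0.45 (SE 0.21, edgeR BH-adjusted p = 0.21) with shNup153-2, from 13.5 ± 1.62 CPM (SD, n = 4) to means of 11 and 9.87. In silenced cultures it stood at 17.9 ± 2.36 CPM (SD, n = 3) with shControl and 16.9 ± 2.61 (SD, n = 3) with shNup153-2, a log2 fold change of -0.09 (SE 0.16). With replicate number as a block the edgeR BH-adjusted p was 0.523, and the value turned to 0.01 without silenced shControl replicate 2 or silenced shNup153-2 replicate 1. Its paralog Hdac2 fell with both hairpins at basal state, by 1.51 (SE 0.22, edgeR BH-adjusted p = 0.00523) and by 1.0 (SE 0.24, edgeR BH-adjusted p = 0.0325) on the log2 scale. Hdac3, whose 3′ UTR holds 1 copy of TGGCTTT, fell with shNup153-1 (-0.99, SE 0.25, edgeR BH-adjusted p = 0.0329), and the class II gene Hdac5, which also holds 1 copy, rose with both hairpins at basal state (1.01 and 1.03). The list of class I deacetylases and their partner subunits did not pass the list test in either basal comparison (edgeR fit, camera BH-adjusted p = 0.372 and 0.984).

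The hairpins were then compared with each other, to separate effects of 1 hairpin from those of both. Oligodendrocyte lineage transcripts made up the largest differences, for which the hairpin and the cell mix of the cultures cannot be told apart. Bcas1, a gene of myelinating oligodendrocytes, stood at 22.5 ± 10.6 CPM (SD, n = 2) with shNup153-1 and 0.063 CPM with shNup153-2, a log2 difference of -8.41 (SE 1.01, edgeR BH-adjusted p = 0.00863). Without shNup153-1 replicate 1 or either shNup153-2 library Bcas1 was not past FDR 0.05 (edgeR BH-adjusted p up to 0.13). Gpr17 had 2 counts with shNup153-2, a shNup153-1 to shNup153-2 ratio of 720 (95% exact interval 199 to 5950), Enpp6, with 2 copies of the 7-base sequence ATAGCTT in its 3′ UTR, a ratio of 237 (65.1 to 1960), Mag, with 1 count, a ratio of 158 (27.9 to 6310), and Patl2, with 3 counts, a ratio of 61.2 (20.5 to 301). Higher with shNup153-2 were the scavenger receptor gene Scarf2 (4.36, edgeR BH-adjusted p = 0.0363), Mei4 (90 and 100 counts, against 0 and 9 with shNup153-1), the hedgehog ligand Dhh (3.92) and Wnt10b (3.64, edgeR BH-adjusted p = 0.0305), with antisense overlap of 25.2% of the exons of Dhh and 12.6% of those of Bcas1. Angpt2 had 3 counts with shNup153-1, a ratio of 19 (6.28 to 94.2), and Angpt2, Scarf2 and Dhh, all lower with shNup153-1, hold 1 copy of TGGCTTT each, as does Gpr17, higher there. Nup153 itself did not differ between the hairpins at FDR 0.05 (-0.85, SE 0.34, edgeR BH-adjusted p = 0.164).

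Between the hairpins, 651 of 14529 genes differed, with 408 higher and 243 lower with shNup153-2. Of the 17 oligodendrocyte markers, 7 were lower with shNup153-2 (15 adjusted over the list alone, camera BH-adjusted p = 1.29e-11, adjusted p = 0.285 with an estimated correlation), and 7 of 62 axon guidance genes were higher and 1 lower, with Sema3a at 1.94 and Slit3 at 2.20 (camera BH-adjusted p = 4.01e-07, adjusted p = 0.793 with an estimated correlation). The count was 998, 381 and 252 without shControl replicates 2, 3 and 4, 4 without shNup153-1 replicate 1, and 0 without either shNup153-2 library, and none of the 10 genes named for this comparison passed FDR with every library left out in turn.

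In silenced cultures the question was what loss of Nup153 does when network activity is blocked. Grsf1, an RNA-binding protein of the mitochondrial granule (chromosome 5, 88659448 to 88676171), fell from 100 to 21.7 CPM, a log2 fold change of -2.21 (SE 0.13, edgeR BH-adjusted p = 0.00283). It also fell with shNup153-2 at basal state (-2.84, SE 0.22), where shNup153-1 left it at 0.01 (SE 0.17, edgeR BH-adjusted p = 0.97), and the hairpins differed (-2.85, edgeR BH-adjusted p = 0.00293). Wnt4, a secreted ligand, rose by 2.01 (SE 0.17, edgeR BH-adjusted p = 0.00633), and Ucp2, a mitochondrial carrier, by 1.87 (SE 0.19, edgeR BH-adjusted p = 0.00915). Atrnl1 fell by 2.23 on the log2 scale (SE 0.23, edgeR BH-adjusted p = 0.00915). Without silenced shControl replicate 1 or shNup153-2 replicate 1 these last 3 calls ended, with edgeR BH-adjusted p up to 0.0656, 0.0812 and 0.0806. Panx2 rose here too, from 48.7 to 158 ± 28.9 CPM (SD, n = 3), and Ndrg1 fell from 348 to 112 CPM.

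Among the other genes named for the largest rise under silencing were Serpind1 (4.03), Card10 (2.59), the cholecystokinin receptor gene Cckbr (2.48), Ak9 (2.35), Nfatc4 (2.29), Cd83 (2.17), Fbxo27 (2.04), Apol8 (1.94) and Ppl (1.90). Card10 stood at -1.71 with shNup153-1 and 0.99 with shNup153-2 at basal state. Among the falls were Rsph4a, of the ciliary radial spoke (-3.28), Mocos, of the molybdenum cofactor (-3.13), Mdfi (-3.11), Trim72 (-2.70), A3galt2 (-2.49), Tnfrsf23 (-2.33) and Xk (-2.17). In all, 654 of 18965 genes changed, with 306 up and 348 down. Residuals of libraries with equal replicate numbers correlated at 0.29, 0.57 and 0.62 across the groups. With 3 libraries per group this does not establish that the numbers pair them. With replicate number as a block 4161 genes changed (2215 up, 1946 down), among them all 654. Without 1 library the unblocked count was 12 (shControl replicate 1), 84 (shControl replicate 3), 4 (shNup153-2 replicate 1), 372 (replicate 2) and 99 (replicate 3). Grsf1 passed FDR with every library left out in turn, and the other 22 of the 23 named genes that were past FDR did not.

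Of 53 potassium and HCN channel genes, 2 rose and 1 fell under silencing, with Kcnc4 at 1.36 (SE 0.12), Hcn2 at 1.12 (SE 0.13) and Kcnj3 at -0.74 (SE 0.13). Adjusted over the list alone, 8 rose and 1 fell, and in the blocked fit 21 rose and 3 fell (camera BH-adjusted p = 0.0208, and 0.00744 in the blocked fit, adjusted p = 0.999 and 0.995 with an estimated correlation). In that blocked fit 12 of 23 cholesterol synthesis genes fell, with Msmo1 at -0.78 (SE 0.06) and Sqle at -0.53 (SE 0.07) (camera BH-adjusted p = 0.0681 without and 0.00423 with the block, adjusted p = 0.999 and 0.995 with an estimated correlation). Of 30 genes of the unfolded protein and integrated stress response, none passed FDR without the block and 6 fell with it, with Atf3 at -2.20 (SE 0.48) and Xbp1 at -0.53 (SE 0.12) (camera BH-adjusted p = 0.0113 without and 0.00744 with the block, adjusted p = 0.999 and 0.995 with an estimated correlation). The vesicular glutamate transporter gene Slc17a6 fell (-1.40, SE 0.14), as did Syt5 (-1.91, SE 0.10), the granin gene Scg3 (-1.83, SE 0.15) and the tRNA exportin gene Xpot (-1.31, SE 0.12). Of these genes, Syt5, Scg3 and Xpot hold the 7-base sequence ATAGCTT in their 3′ UTRs, as do Grsf1 with 3 copies, Atrnl1, Rsph4a and Xk with 2 each, and Tnfrsf23, Kcnj3 and, among the basal falls, Sdha. Genes quoted as rising with shNup153-2 at basal state hold it too, namely Nr4a3, Kcng4, Ephb2 and Cacna1a with 1 copy each. Nup153 itself holds no copy of ATAGCTT there. The sequence was present in 148 of 302 searched genes that fell under silencing and in 9.3% of the others (odds ratio 9.38, 95% interval 7.43 to 11.83). It was picked for its lowest score in this same silenced comparison, so that odds ratio is no independent test. At basal state, in other libraries, it was present in 139 of 551 searched genes that fell with shNup153-2. The immediate early genes had a median of 0.07 in silenced cultures, with none past FDR in the unblocked edgeR fit and 4 that rose and 5 that fell in the blocked one.

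The effect of shNup153-2 was then set side by side in basal and silenced cultures, which share no library. Panx2, Rph3a, Hcn2 and Kcnc4 rose in both states and Ndrg1, Slc17a6, Syt5, Scg3 and Grsf1 fell in both. In all, 181 genes rose and 201 fell in both states and none passed FDR in opposite directions, where chance overlap gives 16.4 and 12.2. Of 1652 genes changed at basal state and tested in both, 1572 (95.2%) had the same sign under silencing. Their median absolute log2 fold change was 1.34 at basal state, the state in which they were chosen, and 0.60 under silencing. With replicate number as a block in the silenced fit, 1118 genes changed the same way in both, among them all 382. The count of 382 became 249 without basal shControl replicate 4, 44 and 50 without either basal shNup153-2 library, 12 and 74 without silenced shControl replicates 1 and 3, and 4, 251 and 83 without silenced shNup153-2 replicates 1, 2 and 3.

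**Figure D4:**
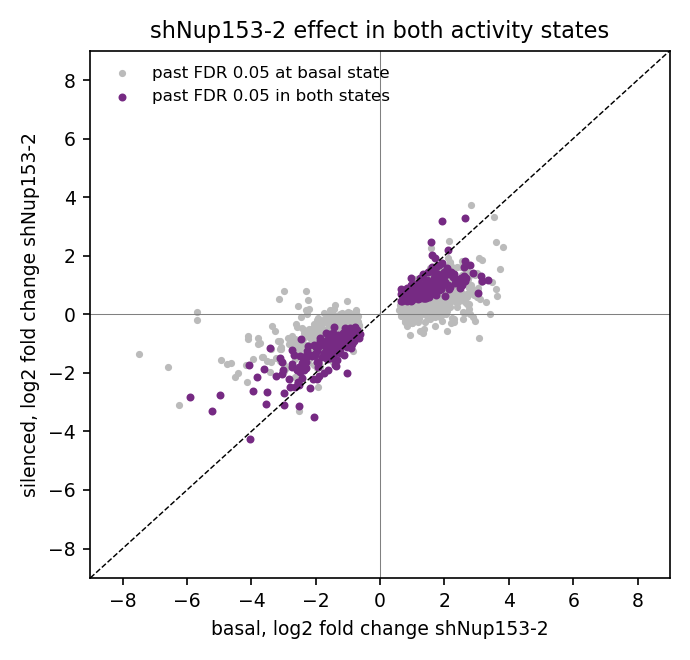
Log2 fold change with shNup153-2 at basal state (x axis) and under silencing (y axis) of the 1652 genes past FDR 0.05 at basal state and tested in both. Purple points mark the 382 genes past FDR in both states, and the dashed line marks equal change.

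Whether the effect differed between the states was tested as an interaction. The amino acid transporter gene Slc7a8 rose with shNup153-2 by 3.06 (SE 0.24) at basal state and by 0.72 (SE 0.14) under silencing, a difference of -2.36 (SE 0.30, edgeR BH-adjusted p = 0.048). Fbxl16 rose by 3.16 (SE 0.21) and 1.12 (SE 0.19), and Rcan2, a regulator of calcineurin, had values of 2.78 (SE 0.21) and 0.74 (SE 0.18), differences of -2.07 and -2.06 with edgeR BH-adjusted p of 0.048 each. These 3 were the only genes past FDR in edgeR, with 2235 at an unadjusted p under 0.05, and DESeq2 gave 230, of which 70 had a positive and 160 a negative difference. The count was 12 without basal shControl replicate 1, 1 without basal shControl replicate 3, 1 without silenced shNup153-2 replicate 3, and 0 without each of the other 11 libraries. Late activity-regulated genes had a median difference of -1.14, with no member past FDR and 13 lower and 1 higher adjusted over the list alone (camera BH-adjusted p = 5.83e-08, adjusted p = 0.0496 with an estimated correlation). Vgf differed by -3.94 (SE 0.64, edgeR BH-adjusted p = 0.0887) and Acan by -3.06 (SE 0.48, edgeR BH-adjusted p = 0.0668). Immediate early genes had a median difference of -1.54, with 16 lower adjusted over the list alone (camera BH-adjusted p = 3.33e-11, adjusted p = 0.195 with an estimated correlation), and potassium and HCN channel genes one of -0.63 (camera BH-adjusted p = 1.77e-08, adjusted p = 0.172 with an estimated correlation). Nup153 had an interaction of 0.10 (SE 0.36, edgeR BH-adjusted p = 0.929).

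The last comparison set silenced against basal shControl cultures, to see the direction of activity-regulated genes on silencing. Fos, an immediate early gene, fell by 3.06 on the log2 scale in silenced cultures (SE 0.71, edgeR BH-adjusted p = 0.0168), and Nr4a2 and Fosl2 stood at -1.21 and -1.60. The proliferation gene Mki67 went from 0.74 to 17.7 ± 13.9 CPM (SD, n = 3), a log2 difference of 4.64 (SE 0.96, edgeR BH-adjusted p = 0.00985), Cdk1 was higher by 4.03 and Aurkb by 4.15. The interneuron peptide genes Sst (-2.73, SE 0.42) and Tac1 (-3.38) and the interneuron gene Reln (-2.27, SE 0.34) fell. Trbc2 had no counts in the silenced shControl libraries, which puts it at least 66-fold lower there at a floor of 3 counts over the group. Also named were Gpr17, with 642, 12 and 391 counts in the silenced libraries and 5 over the 4 basal ones (log2 differences from 7.15 to 11.48 with 1 library left out), and AA474408 (4.03, SE 0.32), both higher, and H2-Ab1 (-6.08, SE 1.00), Prrg4 (-5.84) and Adamtsl4 (-5.80), all lower.

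In all, 1111 genes were higher and 1168 lower in silenced cultures. Of 29 immediate early genes 7 were lower and none higher (median -0.60, camera BH-adjusted p = 0.00105, adjusted p = 0.509 with an estimated correlation), and of 29 late activity-regulated genes 7 were lower and none higher (camera BH-adjusted p = 0.0216, adjusted p = 0.347 with an estimated correlation). Of 22 GABAergic markers 13 were lower (median -1.03, camera BH-adjusted p = 1.72e-07, adjusted p = 0.19 with an estimated correlation), and of 25 progenitor and cell cycle genes 11 were higher (camera BH-adjusted p = 2.94e-05, adjusted p = 0.347 with an estimated correlation). Of 19 oligodendrocyte markers 4 were higher (camera BH-adjusted p = 0.000701, adjusted p = 0.509 with an estimated correlation). The states were deposited in separate tables, so silencing and any difference between the culture series or their processing cannot be told apart in this comparison. The count was 925 and 1027 without silenced shControl replicates 1 and 3.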

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

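Of the tests in this part, only the fit without basal shControl libraries 2 and 4 was chosen after the result was seen. Among the 66 named genes examined in the 4 basal shControl libraries, 3 had a library far from the other 3. This was judged by its gap to the nearest library against the whole range, where chance gives about 5% of genes over both ends together. Alkal2 stood at -1.92 log2 CPM in replicate 1, against -0.17 for the nearest of the others. Fbxo27 had no counts in replicate 2, set to -6.64 by the small constant added, against -0.36 for the nearest of the others. Gpr17 stood at -2.55 in replicate 4 on 5 counts, and the other 3 libraries had no counts and stood at -6.64.

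The effect of shNup153-2 differed between silenced and basal cultures for 3 genes, in the interaction test of edgeR over all libraries. The log2 difference was -2.36 for Slc7a8, -2.06 for Rcan2 and -2.07 for Fbxl16, each with an edgeR BH-adjusted p of 0.048. Slc7a8 went from 13.9 to 116 CPM at basal state and from 31.7 to 52.2 under silencing, Rcan2 from 25 to 172 and from 36 to 60.3, and Fbxl16 from 67.7 to 605 and from 213 to 465. With each of the 14 libraries left out in turn, Slc7a8 stayed past FDR in 2 of 14 fits and Rcan2 and Fbxl16 in 1 of 14 each, with edgeR BH-adjusted p up to 0.242, 0.366 and 0.366, and without basal shControl libraries 2 and 4 together the values were 0.0659, 0.0659 and 0.0979.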

How the results depend on the processing

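Chosen only after the data were seen were the fits on all lines as deposited, on shifted lines, without basal shControl libraries 2 and 4, with a transcript length offset, without genes that hold a hairpin site, and with a replicate block in the silenced fit alone. The other settings were fixed before the data were seen, and among them the scaling by RLE factors and the minimum log2 change of 0.5 kept every gene count within 1.5 times. Of the named genes, none changed direction under another scaling, filter or tool. Hdac1 in silenced cultures turned from -0.087 to 0.00816 without silenced shControl replicate 2 and to 0.00782 without silenced shNup153-2 replicate 1, with a range of -0.20 to 0.00816 over the libraries left out, and was never past the threshold. Named calls were lost in 14 cases with limma-voom, 71 with the replicate block, 3 in fits of only the groups compared, 2 with upper-quartile factors, 1 with lines shifted back, 4 without shControl libraries 2 and 4, and 230 with 1 library left out, and the cause was not tested.

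Gene counts are given for shNup153-1 at basal state, shNup153-2 at basal state, the change shared by both, hairpin against hairpin, silenced shNup153-2, the interaction, silenced against basal shControl, and the change of shNup153-2 shared by both states, in this order. At FDR 0.01 they were 581, 447, 140, 44, 57, 0, 679 and 39, as the stricter threshold requires. With DESeq2 they were 3146, 3491, 1189, 2114, 1845, 230 and, for both states, 1080, with 3410 for silenced against basal shControl within 1.5 times, and the cause was not tested. With DESeq2 51.8% of the genes changed with shNup153-2 at basal state were up, against 61.9% in edgeR, and with the length offset 50%. The interaction gave 5 genes with upper-quartile factors, 6 with no filter, 6 with the filter of 1 CPM and 7 with limma-voom, and the cause was not tested.

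With the replicate block the counts were 0 for both basal comparisons, the change shared by both hairpins, hairpin against hairpin, the interaction and both states, 4161 for silenced shNup153-2 and 19 for silenced against basal shControl. Nup153 stood at -1.70 and -2.57 in the blocked basal fits, where edgeR BH-adjusted p rose to 0.206 and 0.188. The block takes up most of the residual degrees of freedom at basal state, where replicate numbers did not pair the libraries. In the silenced table residuals of equal numbers went together, without pairing being established. With the block there alone 1118 genes were shared by both states.

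On all lines as deposited, where symbols and values of shNup153-1 are out of register, 7997 genes differed with shNup153-1 and 6665 between the hairpins, and 4 and 6 lists passed. A fit of shControl and shNup153-1 alone gave 1203 genes. With the length offset the counts were 2983 for shNup153-1, 976 for both hairpins and 1309 between the hairpins. Without shControl libraries 2 and 4 they were 1877 between the hairpins, 0 for the interaction and 4245 for silenced against basal shControl, with 13 lists for shNup153-1 and 8 for the interaction. The cause was not tested.

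Lists past the threshold numbered 8 for shNup153-1, 12 for shNup153-2, 10 between the hairpins, 2 for silenced shNup153-2, 13 for the interaction and 14 for silenced against basal shControl. With the correlation estimated they numbered 0, 0, 0, 0, 1 and 0, since the estimate widens the test, and with fry, which tests another hypothesis, 3, 2, 1, 0, 3 and 9.

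With 1 library left out the gene counts, in the order above, ranged from 356 to 2050, 106 to 1834, 60 to 546, 0 to 998, 4 to 659, 0 to 12, 925 to 2785 and 4 to 381. Fewer libraries leave fewer degrees of freedom, and beyond that the cause was not tested. The Nup153 change ranged from -2.08 to -1.36 with shNup153-1, from -2.64 to -2.35 with shNup153-2 and from -2.55 to -2.28 under silencing. Numbers of lists ranged from 5 to 11, 9 to 13, 9 to 12, 0 to 5, 10 to 14 and 13 to 16. Simulated changes of 2-fold were found in 7.46%, 5.97% and 34.3% of cases in the 3 knockdown comparisons and in none for the interaction, so changes of that size are mostly not detectable at this depth and number of libraries.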

Other observations

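The tests of network activity, of seed sites, of UTR length and GC content, of the site genes across hairpins, of the shControl site and of the spread between shControl libraries were chosen only after the result was seen. The transcript length offset used below was also added after the data were seen. Other gene lists also passed the camera test with shNup153-2 at basal state, though none did with an estimated correlation. Of 28 p53 target and apoptosis genes 5 fell and none rose, among them the apoptosis genes Hrk (-1.94, SE 0.38) and Apaf1 (-1.24, SE 0.27), with a list median of -0.27 (camera BH-adjusted p = 0.0297, adjusted p = 0.885 with an estimated correlation). Of 25 voltage-gated sodium and calcium channel genes Cacna1a (1.30, SE 0.20) and Scn1a (1.11, SE 0.23) rose and Cacna2d3 (-1.16, SE 0.23) fell (camera BH-adjusted p = 0.0251, adjusted p = 0.885 with an estimated correlation). With the trend of transcript length removed this list was not past the threshold (median 0.14 against 0.38, camera BH-adjusted p = 0.322). A division of the shControl libraries gave a median 0.97 times as far from 0. No member of the astrocyte markers (median 0.48, camera BH-adjusted p = 0.0251) or of the cytosolic ribosomal proteins (median -0.38, camera BH-adjusted p = 0.0297) passed FDR in edgeR. Divisions of the shControl libraries alone gave medians 1.58 and 1.92 times as far from 0 for these lists, and 2.97 times for the p53 list. With the trend of transcript length removed the ribosomal list was not past the threshold (camera BH-adjusted p = 0.415). The chemokine gene Cxcl10 rose with both hairpins, by 4.41 (SE 0.47) and 3.11 (SE 0.52), while the interferon response list did not pass in either basal comparison. The receptor gene Flt1, a vascular marker, fell with shNup153-1 (-4.48, SE 0.66) and holds 1 copy of TGGCTTT in its 3′ UTR.

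Between silenced and basal shControl cultures further groups differed, in a comparison confounded with the culture series. Of 24 neuropeptide and granin genes 11 were lower, among them Gal (-3.70, SE 0.65) and Cartpt (-3.17, SE 0.68) (camera BH-adjusted p = 1.72e-07, adjusted p = 0.19 with an estimated correlation). Of 28 p53 targets 8 were lower, with Perp at -2.28 and Ccng1 at -1.51 (camera BH-adjusted p = 2.56e-06, adjusted p = 0.29 with an estimated correlation), and of 21 reactive astrocyte genes 6 were lower, with Cd109 at -5.19 (camera BH-adjusted p = 2.94e-05, adjusted p = 0.34 with an estimated correlation). Of 28 class I deacetylase and partner genes 4 were higher, among them Mta1 at 0.53, Chd4 at 0.47 and Gatad2a at 0.47 (camera BH-adjusted p = 0.0103, adjusted p = 0.19 with an estimated correlation). Of 53 potassium and HCN channel genes 3 were higher, with Hcn2 at 1.22, and 11 lower, with Kcnc2 at -2.28 (camera BH-adjusted p = 0.00404, adjusted p = 0.494 with an estimated correlation).

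Genes that fell with a hairpin held a 7-base sequence in their 3′ UTRs more often than other genes, with a different lowest-scoring one for each hairpin. The odds ratios do not remove UTR length. With shNup153-2, TGGCTTT gave odds ratios of 1.73 among silenced falls, 1.03 among basal falls and 1.54 among basal rises. With length and GC content removed its scores there were z -1.65 under silencing and -1.58 at basal state. Of all 16384 such sequences, TGGCTTT had the lowest score with shNup153-1 (z -19.92, next unrelated sequence -5.06) and ATAGCTT the lowest with shNup153-2 under silencing (z -24.39, next -6.24). UTR length and GC content were removed from the scores, and ATAGCTT still lay 2.46 times as far from 0 as the lowest unrelated sequence in basal shNup153-2 cultures, which argues against them as the whole cause. For the 84 genes that fell under silencing and hold ATAGCTT but not TGGCTTT, loss of Nup153 is argued against as the main cause. Their median at basal state was -1.02 with shNup153-2 but -0.064 with shNup153-1, where 48 of the 84 lay below 0. For 105 genes that fell under silencing and hold neither sequence, the medians were -1.53 and -0.824, and 83 lay below 0 with shNup153-1. Nup153 itself changed by -1.67 with shNup153-1 and -2.52 with shNup153-2 at basal state, so a need for a stronger loss is not excluded. Genes that hold both sequences are not covered. A candidate explanation is microRNA-like pairing of each hairpin's guide strand, for which ATAGCTT gave an odds ratio of 3.24 among genes that fell in basal shNup153-2 cultures. Among the 578 searched genes changed alike by both hairpins 292 of 372 rises but only 124 of 206 falls hold neither sequence, against 9666 of all 13690 genes searched. GTCGCCC had the highest score with basal shNup153-1, basal shNup153-2 and silenced shNup153-2 (z 9.52, 8.93 and 6.73), each against shControl. Pairing of the shControl hairpin thus stays open for genes that hold it, and 273 rises and 124 falls lack GTCGCCC as well. The hairpin sequences themselves are not in the sources used here.

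Immediate early genes were higher with both hairpins at basal state, though the list did not pass with an estimated correlation (camera BH-adjusted p = 0.805 and 0.864). A chance low level in only some of the shared shControl libraries is argued against. With those libraries divided, the lowest median in 12 comparisons was 0.802. Each division reuses the same 4 libraries, so a chance low level of all 4 together stays open. Direct seed pairing of the shControl hairpin with immediate early genes is argued against only as far as it runs through the candidate sequence GTCGCCC, which 0 of 29 hold. Only 197 of 13690 searched genes hold GTCGCCC, fewer than held any site planted in the simulated test of the search. Its z of 9.52 and 8.93 at basal state stood beside 5.46 and 6.3 for the next unrelated sequences, and related sequences such as TCGCCCA were not counted. Transcript length bias is argued against, since at least 96.7% of each median was kept with the length trend removed. That loss of Nup153 acts through network activity is a hypothesis, which needs a median well under the basal one of 1.22 where activity is blocked, and there it was 0.067, but over members of which 4 rose and 5 fell with the replicate block, which decides nothing. It stays open, as does an indirect effect of the shControl hairpin, since the states were deposited as separate tables and the mix of cell types differed, with oligodendrocyte markers higher in the shNup153-1 and the silenced libraries than in the other basal ones.

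In basal shNup153-2 cultures 12 lists passed the camera test, with channel, protocadherin and synapse genes up and the respiratory chain down, and none of the 12 passed with an estimated correlation. With the trend of transcript length removed 10 of 12 kept their call, which argues against length as the whole cause, but medians shrank from 0.58 to 0.28 for excitatory synapse, 0.56 to 0.31 for presynaptic and 0.51 to 0.20 for axon guidance genes, and with medians from 0.38 to 0.14 and from -0.38 to -0.20 the sodium and calcium channels and ribosomal proteins lost theirs (camera BH-adjusted p = 0.322 and 0.415). Spread between shControl cultures cannot be told apart from the hairpin for 4 of 12 lists (astrocyte markers, p53 targets, respiratory chain and ribosomal proteins), where a division of the shControl libraries into pairs gave medians 1.58, 2.97, 1.74 and 1.92 times as far from 0, and is not excluded for sodium and calcium channels (0.97 times), protocadherins (0.832) and axon guidance genes (0.563). Excitatory synapse, axon guidance and potassium and HCN channel genes were higher with shNup153-2 than with shNup153-1 (camera BH-adjusted p = 2.3e-06, 4.01e-07 and 0.000236, adjusted p = 0.793 each with an estimated correlation) and had medians of -0.28, -0.23 and -0.01 with shNup153-1, so a rise of these lists as a whole was seen with shNup153-2 and not with shNup153-1, although 3, 3 and 8 members rose there. With the length trend removed, the medians of this hairpin difference shrank from 0.742 to 0.376, from 0.664 to 0.483 and from 0.705 to 0.339. The lists stayed past the threshold (camera BH-adjusted p = 0.00049, 0.00049 and 0.00833), and the channel median with shNup153-1 became 0.0784. An effect of shNup153-2 alone and a stronger loss of Nup153 both stay open, since Nup153 with shNup153-2 stood 0.85 (SE 0.34) lower on the log2 scale than with shNup153-1 without passing FDR.

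For silenced shNup153-2 against shControl, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 654 genes and the highest other gave 0. All 10 splits gave at least the 2 lists of the real one, and the highest other gave 16 and the other 3 splits that part all replicate pairs 12, 6 and 3. The cause was not tested. These list counts use the preset correlation, and with the correlation estimated the real split gave 0 lists. These splits are too few for a share under 0.05. For silenced against basal shControl, 1 of 35 splits of the 7 libraries, the real one, gave as many as 2279 genes and the highest other gave 873. A share of 1 in 35 is under 0.05, which argues against chance for the gene count without excluding it. State and culture series go together in the real split, so the splits cannot tell them apart. For the lists 6 of 35 splits gave as many as 14 and the highest other gave 20, so chance cannot be excluded for the number of lists.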
